A study of Homo sapiens with 12 samples.

How the data were processed

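Total RNA (Trizol) of BCPAP cells, an established human papillary thyroid cancer line, was sequenced after transfection with scrambled siRNA (siControl) or siRNA against NOX4 (siNOX4) and culture at 20% oxygen (normoxia) or 1% oxygen (hypoxia). The 4 groups had 3 libraries each, which the labels call biological replicates from separate transfections. Libraries were made with the Illumina TruSeq RNA kit, per the labels. This kit is taken as unstranded here, so a count does not tell overlapping genes on opposite strands apart. How multi-mapping reads were counted is not given in the sources used here, so levels of genes with close copies (AKR1C2, MT1E, the mitochondrially encoded mRNAs) are less certain than others.

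The deposited table held whole-number counts per gene and library, per the file headers and the values. It also held FPKM made by the authors from gene length and a library total, of which the summed counts were 91.0% to 111%. The authors' log2 fold changes and p-values of 4 group comparisons were deposited beside them. The submitters' processing notes list Bowtie 0.12.2 and the builds mm8 and mm9, which are mouse builds, without a role. Counter, annotation and test tool are not given in the sources used here. All 58735 genes of the table had the identifiers, starts and ends of GENCODE 29 (GRCh38). Dates stood in place of 12 gene names, and these were replaced by the names in GENCODE 29. A count in at least 1 library was found for 37380 genes.

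The summed counts per library ranged from 16559386 to 21282835. Counts were fitted with edgeR 4.0.16 in R 4.3.3, using TMM factors (0.903 to 1.09), the filterByExpr filter by group, 1 mean per group over all 12 libraries and the quasi-likelihood F test. Of the genes, 17277 passed the filter. There were 8 residual degrees of freedom per gene, 4.63 prior degrees of freedom and a common biological coefficient of variation of 0.164. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) belong to the fitted log2 fold changes, and levels are library-scaled counts (CPM) after TMM scaling, with SD over n = 3. Principal components used log2 CPM (prior count 2) of the 2000 most variable genes. The comparisons were hypoxia against normoxia within each siRNA, siNOX4 against siControl within each oxygen level, and the interaction of both. The size of the hypoxia response was compared between the siRNAs with fry (limma 3.58.1), over genes called for the average hypoxia effect. These models, the gene lists and the rule for naming genes were set before the data were examined.

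NOX4 was reported first in each comparison. For hypoxia in siControl cells and for siNOX4 at each oxygen level, the named genes were the 5 largest rises and 5 largest falls among protein-coding genes that were called, had a mean of at least 5 CPM in the higher group and showed no overlap between the libraries of the groups. To these came up to 3 called members, by smallest p, of the 8 gene lists with the smallest camera p. The member with the highest CPM among those that were not called could be named for any list. For the interaction, the 5 largest called genes in each direction were to be named. Some genes that the rule names are not reported here. Any other gene named was chosen after its values were seen.

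There were 25 gene lists, written from textbook knowledge. Each was tested with camera (limma) at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, all two-sided and adjusted over the lists of 1 comparison. Camera compares a list with all other genes, and fry asks only whether a list moves 1 way. The interval of the NOX4 count ratio is an exact 95% Poisson interval of the summed counts, offset by library size. Like every interval from counts, it covers counting error only, since PCR copies are counted as molecules. Exact permutation tests on 3 against 3 libraries were two-sided and could not give a p under 0.1.

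Alternatives fixed in advance were other scalings (DESeq2 size factors, upper quartile), no filter, a stricter filter (5 CPM in 3 libraries), a block for the replicate number, each library left out in turn, DESeq2 1.42.0, limma-voom, limma-trend on log2 FPKM with pseudocounts of 1 and 0.1 at an FPKM floor of 1, a fit of only the compared groups and a 2-fold minimum. Added after the data were seen were fits without siControl normoxia replicates 1 and 3, which leave 1 siControl normoxia library and assume that it varies like the other groups, limma-voom with a weight per group, and offsets from a loess curve on gene GC content. The fits were tested on simulated data with 200 changed genes. A scan of 3 prime untranslated regions, also added later, used a siNOX4 score for each of 11711 genes (mean CPM of at least 2). The score was the edgeR p as a normal deviate with the sign of the log2 fold change, bounded at 6 in either direction. It was regressed on the presence of each of 16220 heptamers found in at least 50 genes, with region length and GC content as covariates. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Reported values use all 12 libraries unless the text names those left out or those fitted alone.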

Results

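NOX4, an NADPH oxidase that makes hydrogen peroxide, was silenced in BCPAP cells to ask what part it takes in the response of papillary thyroid cancer cells to low oxygen. NOX4 (ENSG00000086991, GRCh38 chromosome 11, 89324356 to 89498187, minus strand) was counted 8, 13 and 6 times in the siControl normoxia libraries and 1, 5 and 3 times in the siNOX4 normoxia libraries. In hypoxia the counts were 17, 8 and 13 with siControl and 4, 3 and 4 with siNOX4. Mean NOX4 levels were 0.547 ± 0.229 CPM (SD, n = 3) and 0.193 ± 0.135 CPM in normoxia, and 0.627 ± 0.247 CPM and 0.188 ± 0.0289 CPM in hypoxia. The siNOX4 level was 34.9% of siControl in normoxia (95% interval 14.4% to 76.4%) and 30.2% in hypoxia (13.9% to 60.3%). Every siNOX4 library lay below every siControl library at its oxygen level, where chance gives no overlap, in either direction, for 10% of genes at each level. An exact permutation test gave p = 0.1 at each oxygen level, the smallest possible, and p = 0.005 over the 400 regroupings within oxygen levels. In the fit across all genes the log2 fold change of NOX4 was −1.48 in normoxia (SE 0.58, adjusted p = 0.0826) and −1.70 in hypoxia (SE 0.54, adjusted p = 1.00), so neither passed. An effect of hypoxia on NOX4 was not detectable at these counts (0.19, SE 0.47, with siControl and −0.02, SE 0.68, with siNOX4).

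Summed counts were 16904629, 17332339 and 16948208 in siControl normoxia and 17435413, 16559386 and 17752290 in siNOX4 normoxia. They were 17986418, 18466081 and 21282835 in siControl hypoxia and 17969065, 18521972 and 18525579 in siNOX4 hypoxia. The first principal component held 68.2% of the variance and parted the oxygen levels. The second component held 19.8% and parted siControl normoxia replicates 1 and 3 (scores 50.2 and 49.1) from replicate 2 (−20.9) and from the siNOX4 normoxia libraries (−27.1 to −18.6). The genes behind this split, named after their values were seen, included SLC6A12, a betaine transporter, at 178 and 160 CPM in replicates 1 and 3 against 0.495 CPM in replicate 2. PTGS2, the inducible cyclooxygenase, stood at 337 and 359 CPM against 2.66 CPM, and NDRG1, a HIF target, at 252 and 240 CPM against 1532 CPM. Thyroid transcription factors moved apart, with PAX8 at 1735 and 1640 CPM against 533 CPM and NKX2-1 at 43.3 and 46.8 CPM against 136 CPM. The biological coefficient of variation was 31.65% in siControl normoxia, against 7.08%, 5.35% and 8.58% in siNOX4 normoxia, siControl hypoxia and siNOX4 hypoxia. Of markers of other cell types, PECAM1 stood at 30.6 and 22.2 CPM and CD14 at 7.14 and 5.97 CPM in replicates 1 and 3, against 2.66 and 0.804 CPM in replicate 2. TIE1 was lowest there (11.2 and 15.4 CPM against 26.9 CPM), and THY1 was alike in the 3 libraries (88.1 and 75.5 CPM against 81.8 CPM). Other fibroblast and mural markers did differ between libraries. Relative to library size, COL3A1 and COL1A2 peaked in siControl normoxia replicate 3, and DES, PDGFRB, LUM and DCN in replicate 1. RGS5, ACTA2, MYH11, PDGFRA and FAP peaked in libraries other than these replicates.

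**Figure D1:**
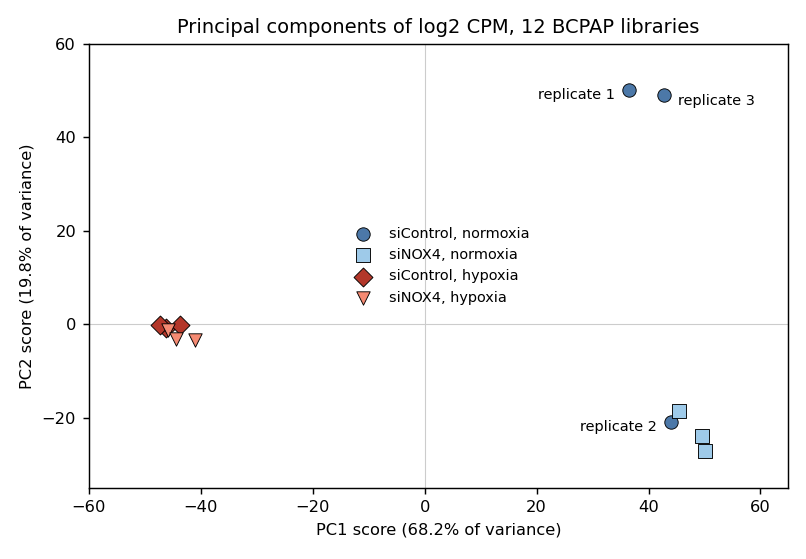
Scores of the 12 BCPAP libraries on principal components 1 and 2 of log2 CPM, 1 point per library. Hypoxia libraries lie together at the left, and siControl normoxia replicates 1 and 3 lie apart from replicate 2, which lies with the 3 siNOX4 normoxia libraries.

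In siControl cells, hypoxia raised KCTD11, an adaptor of ubiquitin ligases that restrains Hedgehog signalling, from 13.2 ± 4.27 to 325 ± 11.5 CPM (log2 fold change 4.62, SE 0.18, adjusted p = 1.2e-08). The oxygen sensor EGLN3, which marks HIF for degradation, rose by 3.20 (SE 0.12, adjusted p = 8.8e-09). CHAC1, which breaks down glutathione, rose from 9.32 ± 5.58 to 132 ± 9.16 CPM (3.81, SE 0.34, adjusted p = 2.9e-06). IL24, a cytokine of the IL-10 family, had the fall with the smallest p, from 175 ± 19.6 to 1.99 ± 0.200 CPM (−6.45, SE 0.15, adjusted p = 5.1e-11). The other largest rises were TREM1 (5.43), a receptor of innate immunity, APLN (4.74), an angiogenic peptide, and PIK3IP1 (4.37), an inhibitor of PI3 kinase. The other largest falls were SLC6A12 (−8.71), the aldo-keto reductase AKR1C2 (−8.48), the kidney and thyroid cadherin CDH16 (−6.52) and the matrix protein TNFAIP6 (−6.23). Without siControl normoxia replicates 1 and 3, AKR1C2 (−1.78, adjusted p = 5.9e-04) and CDH16 (−2.07, adjusted p = 3.8e-05) kept their call at smaller size, and SLC6A12 (−0.90, adjusted p = 0.343) and TNFAIP6 (−2.38, adjusted p = 0.110) lost it. Of the 17277 genes, 9204 (53.3%) were called, 4438 higher and 4766 lower, and 4011 of them changed at least 2-fold. The direction of the majority depended on scaling, since upper-quartile scaling gave 5287 higher and 3961 lower.

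HIF target genes rose with hypoxia in siControl cells, with 23 of 32 measured members higher, 2 lower and 7 not called (camera adjusted p = 2.2e-10; with an estimated correlation, the estimated adjusted p = 0.422). Among them were PFKFB4, a regulator of glycolysis (2.19, SE 0.10), and STC2, a secreted calcium regulator (2.01, SE 0.14), while VEGFA, the angiogenic growth factor, was not called (0.11, adjusted p = 0.679). Glycolysis and lactate export rose (20 of 24 higher, 1 lower; adjusted p = 3.3e-08, estimated adjusted p = 0.422), including the lactate exporter SLC16A3 (1.67, SE 0.10) and PFKFB3 (0.89, SE 0.08). The hexokinase HK1 was not called (0.02). Cell cycle and DNA replication genes rose (22 of 34 higher, 5 lower, 24 and 5 adjusted over the list alone; adjusted p = 1.3e-07, estimated adjusted p = 0.340), including the replication clamp PCNA (51.6 ± 1.81 to 145 ± 5.11 CPM), the helicase subunit MCM6 (1.56) and the ribonucleotide reductase subunit RRM2 (2.54). Of the unfolded protein and integrated stress response, 7 of 20 members were higher and 2 lower (adjusted p = 0.0065, estimated adjusted p = 0.498). They included the stress kinase regulator TRIB3 (1.62), the leucine sensor SESN2 (2.70) and HERPUD1 (1.07) of endoplasmic reticulum degradation, but not the chaperone HSPA5 (−0.14). The call of this list ended without siControl normoxia replicates 1 and 3 (adjusted p = 0.0948), and the median rise went from 1.00 to 0.60 for HIF targets, 0.89 to 0.50 for glycolysis and 0.92 to 0.58 for cell cycle genes, each still called.

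Respiratory chain transcripts fell with hypoxia in siControl cells. Of 13 mitochondrially encoded mRNAs, 10 were lower and 0 higher in edgeR (camera adjusted p = 1.3e-05, estimated adjusted p = 0.534), including MT-CO1 (2146 ± 86.4 to 795 ± 38.0 CPM), MT-CO2 (−1.83) and MT-ND4L (−1.74), while MT-CYB stayed uncalled (−0.02). Mitochondrial transcripts, their ribosomal RNAs included, held 0.886% to 0.989% of the counts in the normoxia libraries and 0.197% (siNOX4 hypoxia replicate 1) to 0.358% in the hypoxia libraries. Of 73 nuclear genes of oxidative phosphorylation, 33 were lower and 8 higher (adjusted p = 0.0213, estimated adjusted p = 0.899), including SDHA of complex II (−1.04) and the ATP synthase subunits ATP5F1A (−0.97) and ATP5F1E (−0.90), but not COX4I1 (−0.11). That list rested on siControl normoxia replicate 2, without which its adjusted p was 0.464, and fry gave it an adjusted p = 0.0535. Its median went from −0.25 to −0.44 without siControl normoxia replicates 1 and 3 (adjusted p = 1.1e-04). Interferon response genes fell, with 12 of 22 lower and 1 higher (adjusted p = 0.0040, estimated adjusted p = 0.422), including the RNA sensor IFIH1 (−1.18, SE 0.11) and the antiviral GTPase MX1 (−2.89), but not IFI27 (−0.38). Cholesterol synthesis fell (13 of 24 lower, 4 higher, 14 and 4 adjusted over the list alone; adjusted p = 0.0242, estimated adjusted p = 0.422), including MSMO1 (−1.33), DHCR7 (−1.18) and SC5D (−0.89), but not MVD (0.09). For the other lists in this paragraph and the HIF, glycolysis and stress lists, the counts adjusted over the list alone were the same as over all genes. None of these list calls passed with an estimated correlation.

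**Figure D2:**
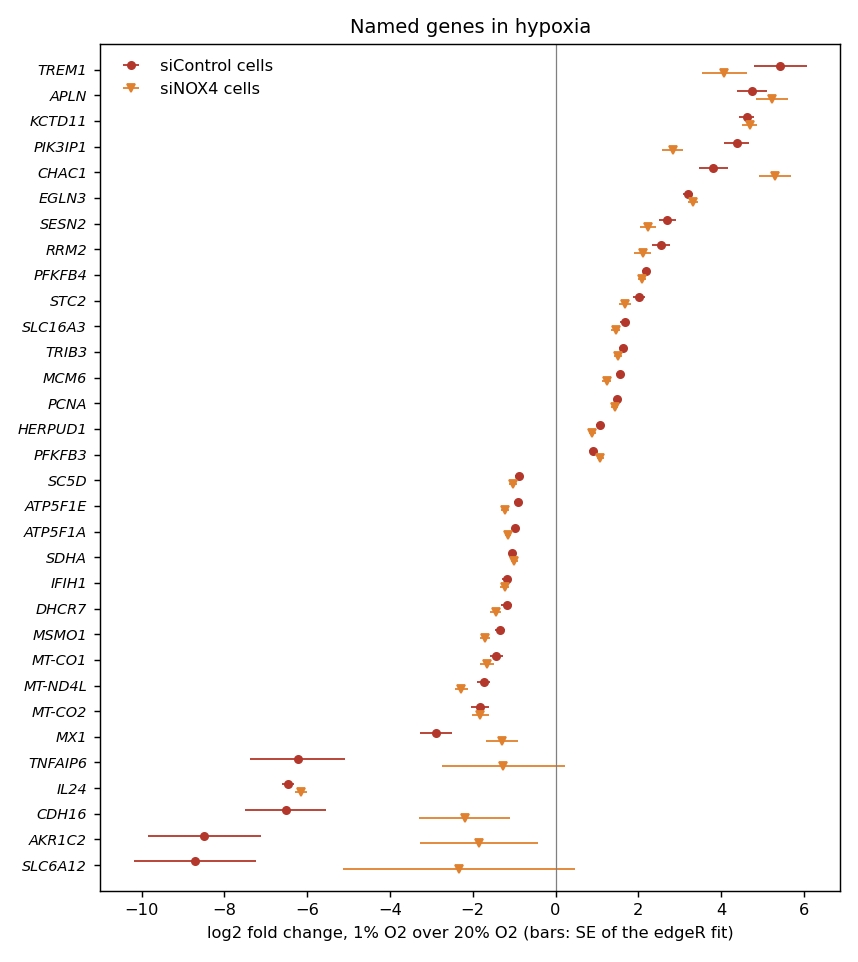
Log2 fold changes of the named genes, 1% over 20% oxygen, in siControl cells (circles) and siNOX4 cells (triangles), with bars of 1 SE of the edgeR fit. KCTD11 and EGLN3 rose in both, and SLC6A12, AKR1C2, CDH16 and TNFAIP6 had wide errors.

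In siNOX4 cells, KCTD11 rose by 4.69 (SE 0.18), APLN by 5.23, EGLN3 by 3.32, CHAC1 by 5.31, TREM1 by 4.08 and PIK3IP1 by 2.83, and IL24 changed by −6.15 (SE 0.14). VEGFA, not called with siControl, rose by 1.05 (adjusted p = 0.00107). SLC6A12 (−2.34), AKR1C2 (−1.85), CDH16 (−2.20) and TNFAIP6 (−1.26) were not called, and none of these differences between the siRNAs passed in the interaction test. Without siControl normoxia replicates 1 and 3, SLC6A12, AKR1C2 and CDH16 were called there (adjusted p = 0.00232, 6.3e-06 and 7.3e-07). The changes of the other named list members lay between −2.28 (MT-ND4L) and 2.23 (SESN2), each called and in the direction seen with siControl. Of the genes tested, 9776 (56.6%) were called, 4970 higher and 4806 lower, and 4452 changed at least 2-fold. With both siRNAs, 3337 genes rose, where independent lists would share 1277, and 3431 fell, where 1326 would be shared. Opposite directions were seen for 3 and 6 genes, where 1235 and 1371 would be shared. Across genes the log2 fold changes of the 2 siRNAs had a Pearson r of 0.782 and a Spearman rho of 0.786, and genes are not independent replicates.

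Oxidative phosphorylation fell in siNOX4 cells (51 of 73 lower, 4 higher, 51 and 5 adjusted over the list alone; adjusted p = 6.0e-09, estimated adjusted p = 0.702), as did the mitochondrially encoded mRNAs (11 of 13 lower; 2.7e-06, estimated adjusted p = 0.572). HIF targets rose (17 of 32 higher, 1 lower; adjusted p = 3.0e-05, estimated adjusted p = 0.702), as did cell cycle genes (17 of 34 higher, 6 lower; 1.7e-04, estimated adjusted p = 0.465) and glycolysis (16 of 24 higher, 1 lower; 7.2e-04, estimated adjusted p = 0.702). Cholesterol synthesis (15 of 24 lower, 3 higher; adjusted p = 6.5e-04, estimated adjusted p = 0.440) and interferon response (15 of 22 lower, 1 higher; 0.0026, estimated adjusted p = 0.501) fell. The stress response list was not called (7 of 20 higher, 5 lower; adjusted p = 0.400). Adjusted over the list alone, the counts of these lists other than oxidative phosphorylation were the same.

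**Figure D3:**
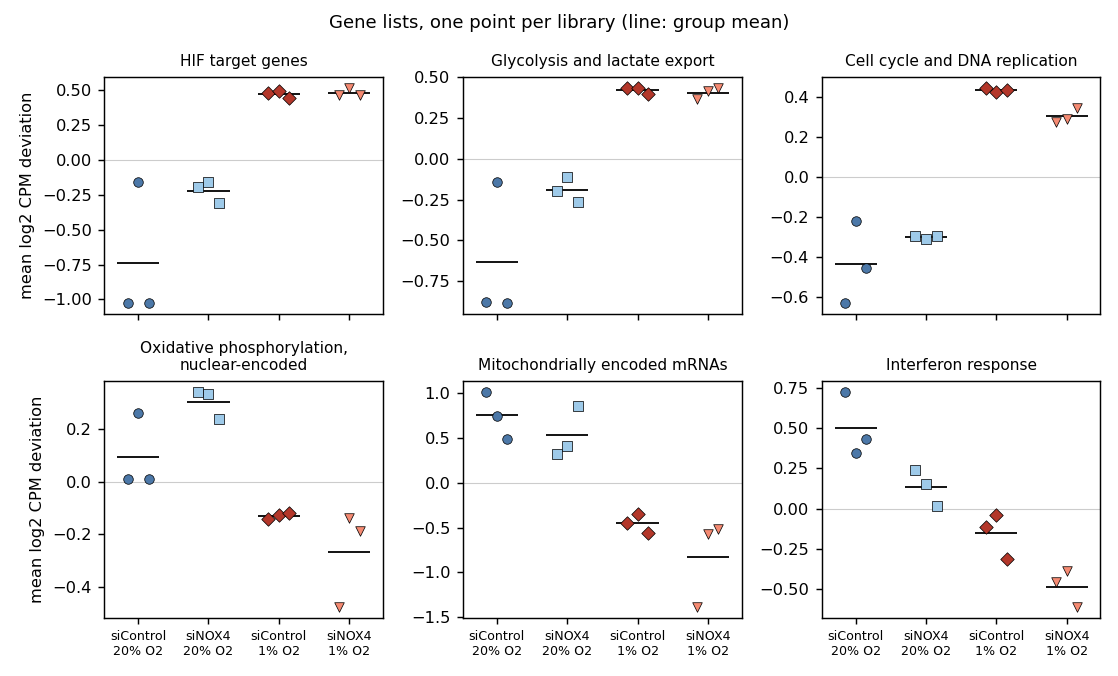
Mean log2 CPM deviation of 6 gene lists from the mean over all libraries, 1 point per library and a line at each group mean (n = 3). HIF targets and glycolysis lie higher in all 6 hypoxia libraries than in all normoxia libraries, and interferon response genes lie lowest with siNOX4 in hypoxia.

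In normoxia, siNOX4 cells had more ZNF267, a zinc finger protein (7.21 ± 2.83 to 22.1 ± 1.14 CPM, log2 fold change 1.62, SE 0.22, adjusted p = 0.0173). PRDX4, a peroxiredoxin that removes peroxide in the endoplasmic reticulum, was higher (1.33, SE 0.27, adjusted p = 0.0302), as were BCL2A1 (1.40), an inhibitor of apoptosis, BCL7A (1.36), a chromatin remodelling subunit, and the metallothionein MT1E (1.28). The largest falls were the unconventional myosin MYO7A (−5.38), the mitochondrial ribosomal gene MRPS24 (−4.75), CDH16 (−4.71), the filament gene BFSP1 (−4.10) and the oestrogen receptor ESR2 (−3.90), each at adjusted p = 0.0302. PTGS2 was lower (233 ± 200 to 3.79 ± 0.485 CPM), as were the cytokines TNF (−1.60) and CXCL1 (−1.30), CAV1 (−1.28) and VEGFA (−0.91). Of 17277 genes, 2593 were called, 686 higher and 1907 lower, 966 of them at least 2-fold. That count rested on single libraries, ranging from 2 (without siNOX4 normoxia replicate 1 or 2) to 9866 (without siControl normoxia replicate 2), and without siControl normoxia replicate 1, siControl normoxia replicate 3 or siNOX4 normoxia replicate 3 it was 6, 3 and 3. Without siControl normoxia replicates 1 and 3, in a fit where 1 siControl normoxia library is left and takes its spread from the other groups, it was 9, of the genes named here only ZNF267 kept its call (1.14, adjusted p = 0.0026), and PTGS2 reversed (0.51). In the authors' deposited adjusted p-values 706 genes were called, 668 of them among the 2593.

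In the list tests of siNOX4 in normoxia, interferon response genes were lower, with IFIT3 (−1.14), MX1 (−1.86) and OAS3 (−0.93) called and 6 of 22 members lower and 1 higher (1 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.0326, estimated adjusted p = 0.548). This call ended without siControl normoxia replicate 1 (adjusted p = 0.0827) or siNOX4 normoxia replicate 3 (adjusted p = 0.0907). Oxidative phosphorylation was higher by a median of 0.19 (4 of 73 higher, 1 lower, 1 and 0 adjusted over the list alone; adjusted p = 1.2e-04, estimated adjusted p = 0.548), with NDUFS6 (0.52) higher and NDUFS1 (−0.59) lower, both of complex I. HIF targets (median 0.44; 2 of 32 higher, 3 lower; adjusted p = 1.9e-04, estimated adjusted p = 0.548) and glycolysis (median 0.41; 0 of 24 members called in edgeR; adjusted p = 5.4e-04, estimated adjusted p = 0.548) were called as higher, and both reversed without siControl normoxia replicates 1 and 3. In fry none of these lists passed (interferon adjusted p = 0.0921, the others 0.116). NF-kB cytokines and targets were not called as a list (0 of 19 higher, 8 lower, 2 and 10 adjusted over the list alone; adjusted p = 0.0561). Without siControl normoxia replicates 1 and 3, against the 1 siControl library left, the interferon list alone was called (median −0.22, adjusted p = 0.0014, estimated adjusted p = 0.577), as lower. Other named members were BAMBI (−1.41), TGFBI (0.83) and CYR61 (0.79) of the TGF-beta targets, CHAC1 (−1.67), XBP1 (−0.40) and HSP90B1 (0.37) of the stress response, and DGAT1 (−0.35) and ELOVL5 (0.43) of lipid synthesis. The calls of all members named in this paragraph ended without siControl normoxia replicates 1 and 3. A fit of only the compared groups called 0 genes.

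In hypoxia, no gene passed for siNOX4 against siControl. The interferon-induced gene IFI27 stood at 373 ± 81.4 CPM with siControl and 246 ± 18.7 CPM with siNOX4 (−0.60, SE 0.18, adjusted p = 1.00). The interferon genes IFI6 (−0.61) and ISG15 (−0.60), named after their values were seen, differed alike, and these 3 passed when adjusted over the list alone. The interferon list was lower by a median of 0.30 log2 units in camera (adjusted p = 7.5e-12, estimated adjusted p = 0.0959), and its mean was lower in each siNOX4 library (−0.46, −0.39 and −0.61) than in any siControl library (−0.11, −0.04 and −0.31). Also called as lower were oxidative phosphorylation (median −0.13, adjusted p = 2.5e-11, estimated adjusted p = 0.410), mitochondrially encoded mRNAs (−0.28, 2.1e-08, estimated adjusted p = 0.365), NRF2 targets (−0.19, 1.0e-04, estimated adjusted p = 0.185) and cell cycle genes (−0.13, 1.0e-04, estimated adjusted p = 0.299). Shifts were also called for scavenging enzymes (−0.11, adjusted p = 0.0014, estimated adjusted p = 0.365), the stress response (−0.13, 0.0061, estimated adjusted p = 0.405) and cholesterol synthesis (−0.08, 0.0061, estimated adjusted p = 0.299). None of these lists passed in fry (interferon adjusted p = 0.278, the others 0.299 to 0.471). Without siNOX4 hypoxia replicate 1 the calls of oxidative phosphorylation, the mitochondrially encoded mRNAs, the stress response (each adjusted p = 0.122) and scavenging enzymes (0.225) ended. The cholesterol call ended without siControl hypoxia replicate 3 (0.116) or siNOX4 hypoxia replicate 2 (0.0888). NF-kB targets (median −0.11) and MAPK output (−0.08) were also called as lower, and the endothelial list (0.15) as higher, without siControl normoxia replicates 1 and 3. With an estimated correlation none of these was called. In the 6 hypoxia libraries alone, camera called NF-kB targets (−0.10, adjusted p = 0.0015, estimated adjusted p = 0.520). It did not call MAPK output (adjusted p = 0.0644) or the endothelial list (0.0516) there. The count of 0 genes in edgeR compared with 448 at an unadjusted p under 0.05, where chance gives 864, with 2 in DESeq2, 2 in limma-trend and 8 in an edgeR fit of the 6 hypoxia libraries. In limma-voom with a weight per group it was 5, and in the authors' deposited adjusted p-values 45 genes were called, 23 higher and 22 lower. Across genes the siNOX4 effects in normoxia and hypoxia had a Pearson r of 0.0923 and a Spearman rho of 0.0927.

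**Figure D4:**
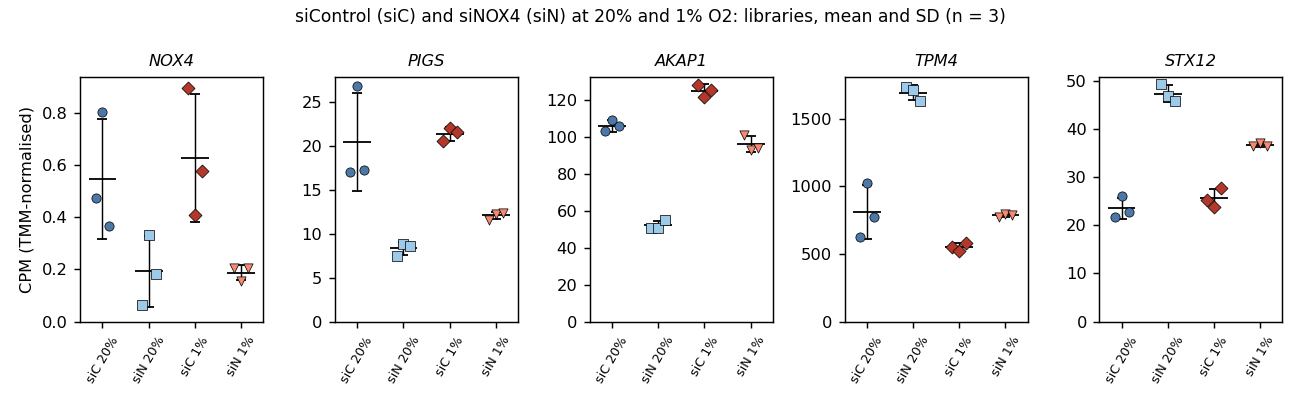
CPM of NOX4, PIGS, AKAP1, TPM4 and STX12 per library at 20% and 1% oxygen with siControl (siC) and siNOX4 (siN), with bars for mean and SD (n = 3). NOX4, PIGS and AKAP1 lie lower, and TPM4 and STX12 higher, in each siNOX4 library than in any siControl library at the same oxygen level.

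The effect of siNOX4 was also compared between the oxygen levels. No gene passed in edgeR for the interaction (smallest adjusted p = 0.159), with 3609 genes at an unadjusted p under 0.05, 61 called in DESeq2 and 7696 called in edgeR without siControl normoxia replicate 2. Over the 11563 genes called for the average hypoxia effect, the median difference in response, signed so that a positive value is a larger response with siNOX4, was 0.05 (fry p = 0.242, and 34 of 100 permutations of the siRNA labels gave a median as large). Over the 4365 genes that changed at least 2-fold the median was 0.11 and fry, not a permutation test, gave p = 0.154. Of the 11563 genes, 45.9% responded less with siNOX4. This difference was −0.03 without siControl normoxia replicate 2.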

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

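The interaction of siRNA and oxygen was planned, and its repeat without siControl normoxia replicates 1 and 3 was chosen only after the result was seen. For 7 gene lists the effect of siNOX4 differed between the oxygen levels in camera (limma), each lower in hypoxia relative to normoxia. Glycolysis and lactate export, the enzymes that turn glucose into lactate, had a median interaction of −0.37 (adjusted p = 4.0e-04). HIF target genes, which low oxygen turns on, had −0.40 (adjusted p = 4.0e-04), and nuclear genes of oxidative phosphorylation, the respiratory chain, had −0.32 (adjusted p = 1.8e-11). The unfolded protein and integrated stress response had −0.33 and peroxide and superoxide scavenging enzymes −0.29 (both adjusted p = 0.0035). Cholesterol synthesis and uptake had −0.30 and cell cycle and DNA replication −0.23 (both adjusted p = 0.0396). With an estimated correlation none of the 7 was called (adjusted p of 0.510 to 0.514), nor in fry (adjusted p of 0.131 to 0.254), and in edgeR no member passed over all genes or adjusted over the list alone.

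In normoxia, siControl replicates 1 and 3 had lower HIF targets than replicate 2, such as CA9, the tumour carbonic anhydrase (8.80 and 7.55 CPM against 35.6 CPM in replicate 2). Without these libraries, which leaves 1 siControl normoxia library, HIF target genes and glycolysis reversed (medians 0.03 and 0.05). The calls of the stress response (−0.11), cholesterol synthesis (−0.08) and cell cycle genes (−0.06) ended. Those of oxidative phosphorylation and scavenging enzymes stayed at smaller medians (−0.18 and −0.20). NF-kB targets, not called with all libraries (camera adjusted p = 0.179), were called as lower (−0.17). With an estimated correlation no list was called in this repeat. With the other libraries kept, the cholesterol call also ended without siControl hypoxia replicate 3 (camera adjusted p = 0.0736) or siNOX4 hypoxia replicate 2 (0.0637). The call of cell cycle genes ended without siControl normoxia replicate 1 (0.122), siNOX4 normoxia replicate 3 (0.0562) or siNOX4 hypoxia replicate 1 (0.0553). Oxidative phosphorylation was lowest in siNOX4 hypoxia replicate 1 (mean log2 deviation −0.48 against −0.14 and −0.19 in replicates 2 and 3).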

How the results depend on the processing

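Most named hypoxia genes kept their direction and call, while siNOX4 calls in normoxia were often lost. The fits without siControl normoxia replicates 1 and 3, with a weight per group and with GC offsets were chosen only after the result was seen. For the genes named in hypoxia with siControl, 732 of 740 values under an alternative kept direction and call, and with siNOX4 720 of 739. For siNOX4 in normoxia 435 of 832 did, 394 losing the call and 1 reversing, and in hypoxia 188 of 220, with 32 gaining a call. SLC6A12, AKR1C2 and CDH16 lost the hypoxia call of siControl cells in limma-voom. Of the list tests, 125 of 136 were kept in siControl hypoxia, 128 of 136 in siNOX4 hypoxia, 111 of 136 for siNOX4 in normoxia, 122 of 144 for siNOX4 in hypoxia and 106 of 136 for the interaction.

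With a 2-fold minimum 4011 and 4452 hypoxia genes (siControl, siNOX4) and 966 siNOX4 genes in normoxia remained. The counts of siNOX4 genes in normoxia, siNOX4 genes in hypoxia and interaction genes were 2593, 0 and 0. They became 4696, 15 and 2107 with no filter, 9, 27 and 2 without siControl normoxia replicates 1 and 3, and 3986, 2 and 61 in DESeq2. In normoxia limma-voom called 9, limma-trend 46 (pseudocount 1) and 18 (pseudocount 0.1), voom with a weight per group 1323 and a fit of the compared groups 0. In hypoxia limma-trend called 2 with either pseudocount, voom with a weight per group 5 and a fit of the compared groups 8, and limma-trend (0.1) called 4 interaction genes. Over each library left out, siNOX4 genes in normoxia ranged from 2 to 9866, siNOX4 genes in hypoxia from 0 to 12 and interaction genes from 0 to 7696, the highest each without siControl normoxia replicate 2. With the replicate number as a block (replicate block) the counts were 9056 and 9679 hypoxia genes and 2617, 0 and 0. Deviations of libraries with equal numbers had r of −0.058 to 0.150, over 0.1 in 2 of 18 pairs. Of the 12 libraries, 8 correlated best with a library of their own number, a hint from the data that equal numbers may pair. The labels do not say that they do, so the main fit took no pairing. The simulated libraries were drawn independently, without the joint shift of siControl normoxia replicates 1 and 3, so they cannot give the number of false calls in the data. With uneven spread in simulated data, the fit of all 12 libraries made 137 false calls for siNOX4 in normoxia and the fit of the compared groups 3. At 2-fold in normoxia these fits recovered 80% and 22% of changed genes. At 1.5-fold in hypoxia these fits recovered 18% and 76% of changed genes, so the shared spread itself lowers the hypoxia count. The cause of the other changes was not tested.

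Genes called for siNOX4 at both oxygen levels numbered 0, 53 with unadjusted p in hypoxia (6 more in opposite directions) and 5 without siControl normoxia replicates 1 and 3. NOX4 itself kept its direction with siNOX4 under both other scalings, no filter, the replicate block, each library left out, without siControl normoxia replicates 1 and 3, and in DESeq2 and limma-voom. Its hypoxia effect reversed in siControl cells without those libraries (−0.36) and in siNOX4 cells with upper-quartile scaling (0.0553) and limma-voom (0.13), and ranged from −0.13 to 0.57 and from −0.43 to 0.57 over libraries left out. PTGS2 reversed without siControl normoxia replicates 1 and 3 (0.51). So did HIF targets (adjusted p = 0.157), glycolysis (0.183), NF-kB targets (0.445), TGF-beta targets and the stress response (both 0.653) and fatty acid synthesis (0.476) for siNOX4 in normoxia, and glycolysis (0.369) and HIF targets (0.0811) in the interaction. List calls numbered 34, 0 with an estimated correlation, 30 in fry (each for hypoxia, 0 for siNOX4 or the interaction) and 29 to 51 over libraries left out. The difference in response size ranged from −0.0282 (without siControl normoxia replicate 2) to 0.0750 over libraries left out, and was 0.113 with a 2-fold minimum. Upper-quartile scaling moved the median of all genes by 0.118 in siControl hypoxia and made 57.2% of the calls higher, against 48.2%. NOX4, at most 17 counts per library, is limited by depth.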

Other observations

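The genes in the first paragraphs were chosen after their values were seen, as were all tests of explanations apart from the splits of the libraries. No gene passed the interaction test in edgeR, so unequal values with siControl and siNOX4 do not show a different response. The siControl values rest on the uneven siControl normoxia libraries. In hypoxia, BCPAP cells raised HMOX1, which degrades haem, from 42.6 to 561 CPM with siControl (log2 fold change 3.72, and 3.38 with siNOX4) and lost FTH1, the ferritin heavy chain that stores iron (−1.39 and −1.75). TXNRD1, a thioredoxin reductase of the NRF2 programme, rose (1.14 and 0.57), but of 20 NRF2 targets 6 were higher and 5 lower with siControl, and 5 higher and 9 lower with siNOX4. CYBA, the membrane partner that NOX4 needs, rose from 233 to 617 CPM with siControl (1.41) and by 0.82 with siNOX4. HIF1A mRNA fell (−1.88 and −1.12), as the coactivator EP300 (1.17 and 1.78) and the oxygen sensor EGLN1 (0.99 and 0.89) rose. Of 27 collagens and matrix enzymes, 15 were higher and 7 lower with siControl, and 13 and 5 with siNOX4. LOX (2.07 and 1.48), P4HA2 (2.00 and 1.16), PLOD2 (1.37 and 1.40) and the collagen chaperone SERPINH1 (1.83 and 0.99) rose, while the collagens COL8A1 (−1.79 and −1.79) and COL5A2 (−1.65 and −1.29) fell.

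SNAI2, a repressor of epithelial genes, fell from 312 to 43.7 CPM with siControl (−2.83, and −2.43 with siNOX4), and so did SNAI1 (−1.56 and −1.45). Of 20 genes of MAPK output, 6 were higher and 4 lower with siControl and 7 and 6 with siNOX4, with IER3 (−3.49 and −2.86), SPRY2 (−2.16 and −1.98) and DUSP4 (−1.46 and −1.40) lower and MYC higher (2.31 and 1.73). Of 19 NF-kB cytokines and targets, 7 were higher and 8 lower with siControl and 8 and 5 with siNOX4. The cytokines IL1A (−2.11 and −1.60), IL1B (−1.72 and −1.87) and CXCL8 (−1.96 and −1.29) fell and the adhesion receptor ICAM1 rose (1.79 and 1.55). GDF15, a stress cytokine, fell (−2.53 and −3.76). Of thyroid genes, the transcription factor FOXE1 rose (1.46 and 1.09) and the thyroid hormone receptor THRA fell (−0.91 and −0.88). Lists of these groups were not called for siControl in camera, with adjusted p = 0.404 for epithelial-mesenchymal transition, 0.0901 for collagens and matrix enzymes, 0.468 for thyroid differentiation, 0.982 for NF-kB targets and 0.999 for MAPK output. Epithelial-mesenchymal transition was called as lower without siControl normoxia replicates 1 and 3 (median −0.28) and collagens and matrix enzymes as higher (0.54). With siNOX4, camera with all libraries gave these lists adjusted p = 0.0875 and 0.341, and both were called without those replicates (−0.38 and 0.60). None of these calls was kept with an estimated correlation. The epithelial-mesenchymal list held epithelial genes such as CDH1 and mesenchymal genes such as VIM, so its direction does not describe a transition.

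Splits of the libraries were planned. For hypoxia with siControl the real split called 9204 genes and the highest of the other splits 0, and for hypoxia with siNOX4 9776 and 0, so 1 of the 10 splits gave as many in each. For siNOX4 in normoxia 2 of 10 splits gave as many, the real one 2593 and the highest other 3529. That other split set siControl replicates 1 and 3 with siNOX4 replicate 3 against the rest, which points to a structure of the libraries. For siNOX4 in hypoxia all 10 splits called 0. With 10 splits a share under 0.05 cannot be reached. For the interaction the real count was 0, so 100 of 100 drawn regroupings gave as many (highest other 6) and the test says nothing, as for siNOX4 in hypoxia. For the size of the hypoxia response, 34 of 100 gave a median as large as 0.0496 (highest other 0.0909), so chance was not excluded.

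The pattern weighed first was that siControl normoxia replicates 1 and 3 carried much SLC5A3 (myo-inositol transporter, 5106 and 5290 CPM against 624 CPM in replicate 2), AKR1B1 (aldose reductase, 4229 and 3755 CPM against 533 CPM) and the amino acid transporter SLC38A2 (3302 and 3871 CPM against 896 CPM). Labels exchanged among the 4 groups were excluded only as far as 2 genes go, both chosen after their values in these libraries were seen. AKAP1 was at least 102.9 CPM in both against at most 54.9 CPM in siNOX4 normoxia, and IL24 at least 170.9 CPM against at most 3.31 CPM in hypoxia. AKAP1 was also lower with siNOX4 in the 6 hypoxia libraries fitted alone (−0.38), which hold neither of the replicates in question. Cells of another line in place of BCPAP cells were excluded too. Of 8754 genes at 10 CPM or more in each of the other 4 normoxia libraries, 0 were below 1 CPM in both. Cells mixed with BCPAP cells were not excluded. Among genes that passed the filter, 8 genes at 10 CPM or more in both were below 1 CPM in each of the other 4. The filter by group dropped genes found in both of these libraries alone, so this count is a lower limit and cannot decide. Higher tonicity of the culture medium may have acted, as 6 of 8 osmotic genes were higher in both libraries. SLC6A6 was lower (179 and 207 CPM against 262 to 305 CPM in the other 4). HSPA4L was lower by little (9.27 and 9.93 CPM against 9.99 to 13.9 CPM), and the test did not decide. Wrong labels from outside the 4 groups on both libraries, or another difference in culture, stayed open, and no other biological explanation was tested.

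The pattern weighed next was the change of more than 50% of the genes, from PCNA to MT-CO1, with a trend on GC content (Spearman rho across genes 0.218 with siControl and 0.227 with siNOX4). GC content bias was excluded as the whole cause. With offsets that lowered rho to 0.0136, edgeR called 9001 genes with siControl, 7904 of them also called without the offsets and all 7904 in the same direction. With siNOX4 the count was 9549 and rho 0.0212. A response to oxygen is the biological explanation that the design names, and this comparison was planned, but it was not tested in other libraries. The trend on GC content was found and tested on the same libraries.

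The last pattern was a small set of genes that siNOX4 moved alike at both oxygen levels. PIGS, a subunit of the GPI transamidase, was lower in normoxia without siControl replicates 1 and 3 (−1.69, SE 0.13) and in the 6 hypoxia libraries fitted alone (−0.82, SE 0.09), as was AKAP1, a mitochondrial anchor of protein kinase A (−1.07 and −0.38), while the syntaxin STX12 (0.86 and 0.52) and the tropomyosin TPM4 (0.73 and 0.52) were higher. Noise of the uneven siControl normoxia libraries was excluded as the whole cause, since 9 genes were called in normoxia against the 1 siControl library left, 4 of the 9 were also called in the 6 hypoxia libraries, which hold none of the uneven ones, and all 9 had the same sign there, 7 at an unadjusted p under 0.05. A candidate explanation of a shift across many genes, not of this set, is matches of the siRNA guide seed. Genes with TGGATAA in the 3 prime untranslated region had the lowest adjusted shift in score of 16220 heptamers in hypoxia (z −7.885, lowest of 100 shuffles −4.812). In normoxia this heptamer had rank 1 against siControl replicate 2 (z −5.745), but rank 340 (z −2.168) against all siControl normoxia libraries. Shuffling treated genes as independent, and the unrelated heptamer GGCTCAA (z −4.817 in hypoxia) also lay below all shuffles, so these set no firm limit. Unadjusted median log2 fold changes of the 490 genes with the joined octamer TTGGATAA were 0.00995 in hypoxia and −0.00424 in normoxia against siControl replicate 2. Genes without a site had −0.00820 and −0.000463. Direct repression cannot account for the whole set, since STX12 and TPM4 were higher, which was known before this test. Of the 13 genes called at either oxygen level, 4 were lower at both. Of these, 2 held either of the lowest heptamers in the 3 prime untranslated region, as 18.85% of scanned genes did. They were PIGS and, by sign alone, MAGED1 (−0.06 in hypoxia, adjusted p = 0.774, and 0.02 with all normoxia libraries, adjusted p = 0.965 in edgeR). AKAP1 held neither, while STX12 and TPM4, which were higher, also held either heptamer. Of the 13 genes, 4 held either heptamer and 12 lacked the octamer. PIGS held the octamer there, so direct repression of PIGS stayed open. NOX4 holds the octamer in a coding exon (chromosome 11, 89449490 to 89449497), as 6.99% of scanned genes do anywhere in the transcript, and a response to low NOX4 stayed open.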
